A study of Homo sapiens with 3 samples.

How the data were processed

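Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where Mtg16 and E2-2 sit on the genome of CAL-1 cells. CAL-1 is an established human cell line with features of plasmacytoid dendritic cells. The series holds 3 libraries, 1 made with an antibody against Mtg16, 1 with an antibody against E2-2 and 1 of input chromatin. A peak list and a list of subpeaks were analysed for each of the Mtg16 and E2-2 libraries, and the input library was not analysed here. Groups were taken from the sample titles. With 1 library per antibody there is no measure of the spread between cultures, so no p-value between libraries was computed.

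Per the labels' protocols, chromatin was sheared by sonication, complexes were isolated with the antibody, and the DNA was sequenced as single-end reads on an Illumina instrument. Per the submitters' processing notes, Bowtie2 2.0.0 and the human build hg19 were used. The deposited peaks are numbered MACS peaks, so the authors called them with the peak caller MACS. Its version, its settings and whether the input served as its control are not given in the sources used here. Each deposited peak has a score that the authors' caller gave it. The lowest score is 50 in both lists, and no header or label states the scale of the score. In the E2-2 list 134 peaks share a score of exactly 3100 and 13 lie above it, so the score does not order the strongest E2-2 peaks well. The scores were compared only within a list. Per the labels, the subpeak lists were made by splitting the peaks. Each deposited subpeak has a height, a signal that takes whole numbers of at least 5, and a summit position. Subpeak starts lie on a grid of 10 bp in both lists, which limits the precision of summit distances. Nothing states that the heights were scaled to sequencing depth. The number of reads per library is unknown from the peak lists, so heights and list sizes of the 2 libraries carry an unknown difference in depth. Peaks were called on single libraries, with no pooling stated.

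Each subpeak was attached to the peak it overlapped most, and a peak took the height and summit of its tallest subpeak. In the Mtg16 list 69 peaks had no subpeak and stayed out of measures that need a height or a summit. A peak was called shared when it overlapped a peak of the other list by at least 1 bp, and separate otherwise. Shares of peaks are given with 95% Wilson intervals, and ratios of median scores with 95% bootstrap intervals from 1000 draws. Both cover sampling of peaks within a library only, treat peaks as independent and say nothing of replicate cultures. The overlap was compared with 1000 random placements of the peaks of one list, each on its own chromosome or contig with its width kept. Placement ran from the first to the last peak of either list, since chromosome lengths and assembly gaps were not used here. The one-sided p counts placements with an overlap at least as high, and 0.0010 is the smallest it can give. Summit distances at overlapping pairs were compared with 1000 draws of summits at random within the same peaks. They were also compared with 1000 draws exchanging relative summit positions among the peaks of each list, and with 1000 draws moving each Mtg16 peak within reach of its E2-2 peak, both added after seeing the data. Peak coordinates are printed 1-based on hg19, with 1 added to the start of each peak as deposited. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.

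The comparisons, tests, 22 gene lists, 22 motifs and most alternatives were fixed before the data were examined. The random placement of the overlap test departs from that plan, which had it outside assembly gaps. The planned shares of promoters, exons and introns, the motif shares, the gene lists and the random placement matched on distance to a gene start need an hg19 annotation or sequence. These were not used here, so no peak was assigned to a gene. The rule for named genes was therefore applied to peaks. It took the 10 highest scores in each list and the 10 overlapping pairs with the lowest sum of ranks, with ties ordered by height and peaks off chromosomes 1 to 22, X and Y left out. Other regions that the text singles out were chosen after their values were seen. The alternatives were peaks at or above the median score, a minimum score of 100, an overlap of at least 50% of the shorter peak, tallest summits within 200 bp, subpeaks in place of peaks, removal of contigs and wide peaks, and several other random placements or subsets of E2-2 peaks. The overlap count was tested on simulated data. Of 3206 simulated Mtg16 peaks of which 70.0% were planted on E2-2 peaks, 70.2% were found to overlap. In a separate simulation of 3206 peaks with no planted overlap, 0.780% did. For heights at 216 sites simulated with counting noise only, the variance used in the closing comparison of heights averaged 1.01 times the counting variance.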

Results

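The series mapped Mtg16 and E2-2 in CAL-1 cells, and its title places both in the control of E protein activity and of the choice between dendritic cell lineages. E2-2, encoded by TCF4, is a basic helix-loop-helix transcription factor of the E protein family that plasmacytoid dendritic cells need. Mtg16, encoded by CBFA2T3, is a transcriptional corepressor of the ETO family that reaches DNA through other proteins. The design implies 1 comparison, between the sites of the corepressor and those of the transcription factor. Each antibody was represented by 1 library, so no difference given here has a replicate check.

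The E2-2 library gave 21382 peaks and the Mtg16 library 3206, 6.67 times fewer. The E2-2 peaks covered 9.85 Mb and the Mtg16 peaks 0.998 Mb. E2-2 peaks had a median width of 406 bp (interquartile range 316 to 528) and Mtg16 peaks one of 271 bp (230 to 358). Most peaks held a single subpeak, 76.8% of those of E2-2 and 85.9% of those of Mtg16. The median subpeak height was 10.0 in the E2-2 list (7 to 17) and 7 in the Mtg16 list (6 to 10). The number of reads behind either list is unknown, so the difference in list size carries any difference in depth.

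Most Mtg16 peaks overlapped an E2-2 peak, whereas at most E2-2 peaks no Mtg16 peak was called. Of the 3206 Mtg16 peaks, 2298 overlapped an E2-2 peak, which is 71.7% (95% Wilson interval 70.1 to 73.2). These were matched by 2191 of the 21382 E2-2 peaks, or 10.2% (9.85 to 10.7). Of the shared Mtg16 peaks, 93.5% lay wholly within an E2-2 peak. Random placement of the Mtg16 peaks gave a mean of 29.7 overlaps and at most 52 in 1000 placements. The observed number was 77.5 times that mean (permutation of positions, one-sided p = 0.0010, the smallest that 1000 placements can give). The ratio was 30 when each peak was moved by only 10 to 100 kb, a placement added after seeing the data that keeps the local density of sites. It was 68.5 with placement outside stretches of over 2 Mb without a peak of either list, also added after seeing the data. A Mtg16 signal below the limit of the peak caller is not in the list, so an E2-2 peak with no Mtg16 peak is not shown to lack Mtg16.

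Shared peaks were the stronger E2-2 peaks on average. In the E2-2 list, shared peaks had a median score of 921 (95% interval of the median 888 to 957) and separate peaks one of 99.7 (98.4 to 101), a ratio of 9.24 (95% bootstrap interval 8.83 to 9.63). The ratio was 5.81 among peaks at or above the median score of each list. The median height was 46 at shared E2-2 peaks and 11 at separate ones, and the median width was 719 bp against 389 bp. More than 1 subpeak was present in 52.4% of shared and in 19.8% of separate E2-2 peaks. Of the 4276 E2-2 peaks of highest score, 20% of the list, 1926 were shared, or 45.0% (43.6 to 46.5). In the next 20% by score 3.91% were shared, and in the lowest 20% only 0.585%.

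The share of E2-2 peaks with a Mtg16 peak rose with E2-2 height in every height class. It was 0.398% of 7544 peaks at heights of 5 to 9 and 12.6% of 2423 peaks at 20 to 29. It reached 55.1% of 606 peaks at 40 to 49 (51.1 to 59.0) and 89.3% of 391 peaks at 60 to 79 (85.8 to 91.9). Of the 216 E2-2 peaks with a height of at least 100, 215 overlapped a Mtg16 peak, and the remaining one lay on an unplaced contig. Among the 16109 E2-2 peaks with a height under 20, 213 did, or 1.32%.

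**Figure D1:**
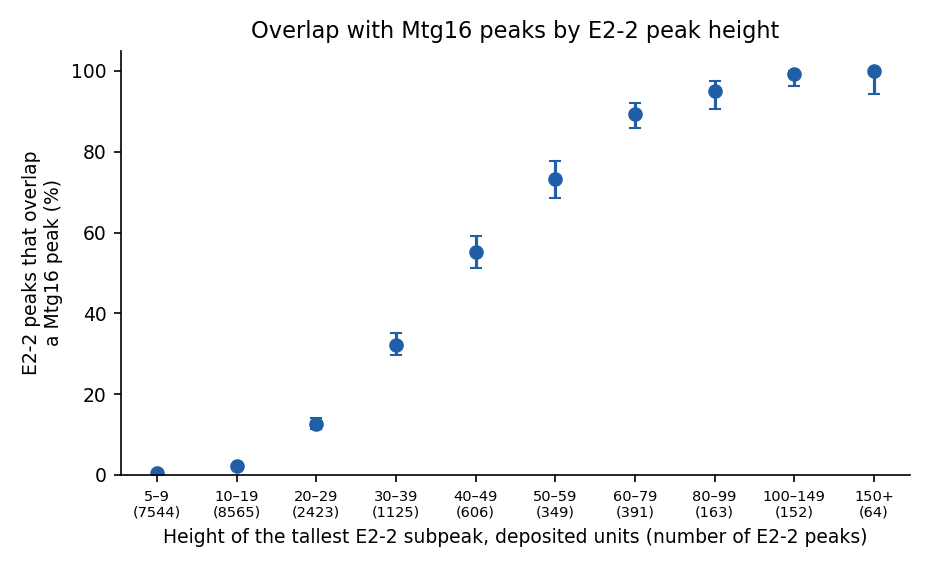
Share of E2-2 peaks that overlap a Mtg16 peak (y axis, percent) by the height of the tallest E2-2 subpeak (x axis, deposited units, with the number of peaks per class); points are shares in 1 library pair and bars are 95% Wilson intervals. The share climbs from 0.398% at heights of 5 to 9 to 55.1% at 40 to 49 and 99.3% at 100 to 149.

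Within the Mtg16 list, too, the shared peaks scored higher. Their median score was 87.5 (84.8 to 90.5) against 55.6 (55.0 to 55.7) for the 908 separate peaks, a ratio of 1.57 (1.53 to 1.62). Of the 641 Mtg16 peaks of highest score, 20% of the list, 638 were shared, or 99.5% (98.6 to 99.8). Of the 642 lowest, with scores from 50 to 54.6, 36.6% were shared. Only 9 separate Mtg16 peaks scored 100 or more, against 975 shared ones. Separate Mtg16 peaks were also narrower, with a median width of 231 bp against 309 bp. By Mtg16 height the share did not keep rising. It was 63.3% of 2172 peaks at heights of 5 to 9, 95.2% of 783 at 10 to 19 and 89.8% of 128 at 20 to 29. All 27 peaks at 30 to 39 were shared, but only 3 of 5 at 100 to 149, and the 1 peak of 150 or more was separate. That peak lay at the start of chromosome 9. These classes include contigs, and a Mtg16 height of 147 was on the unplaced contig GL000225, where 5 of 14 Mtg16 peaks were shared.

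**Figure D2:**
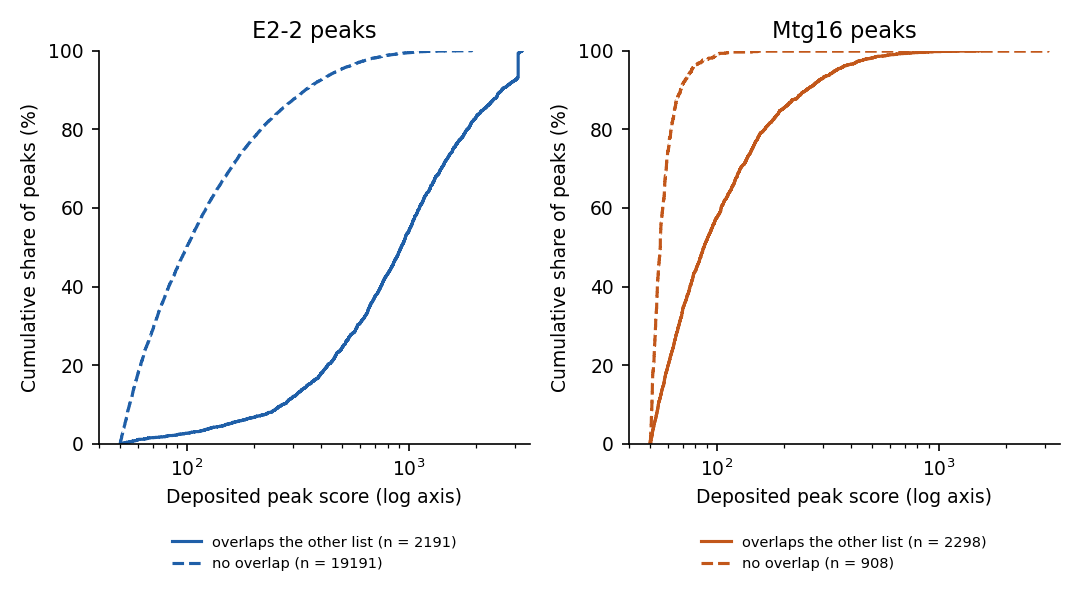
Cumulative share of peaks (y axis, percent) by deposited peak score (x axis, log scale) in the E2-2 list (left) and the Mtg16 list (right), with solid lines for peaks that overlap the other list and dashed lines for peaks that do not. Shared peaks lie to the right in both lists, with median scores of 921 against 99.7 for E2-2 and 87.5 against 55.6 for Mtg16; the vertical step in the E2-2 panel is the 134 peaks with a score of exactly 3100.

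At shared sites both summits lay close together. Over 2289 overlapping pairs with a summit in both lists, the median distance between the tallest Mtg16 and E2-2 summits was 30 bp (interquartile range 10 to 60). Summits drawn at random within the same peaks gave a median of 192 bp, between 180.2 and 204 bp over 1000 draws. The summits lay within 100 bp of each other in 87.0% of pairs (85.6 to 88.3) against 27.2% at random, and within 50 bp in 72.3% against 13.7%. Summits are not spread evenly within peaks, so this comparison overstates the distance that overlapping peaks give by chance. With the relative summit positions exchanged among the peaks of each list, chosen after seeing the data, the random median was 105.5 bp (98.3 to 112 over 1000 draws), and 47.9% of pairs lay within 100 bp (one-sided permutation p = 0.0010 for the median, the smallest possible).

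**Figure D3:**
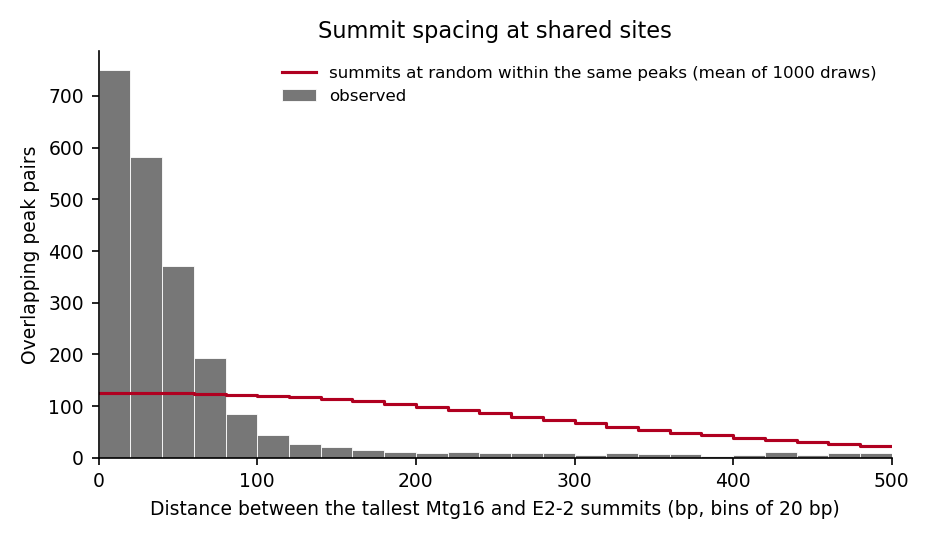
Number of overlapping peak pairs (y axis) by distance between the tallest Mtg16 and E2-2 summits (x axis, bp, bins of 20 bp up to 500 bp); bars are the observed pairs and the line is the mean of 1000 draws of summits at random within the same peaks. The observed median is 30 bp and the random median 192 bp, and 750 pairs fall in the first bin against 126 at random.

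Taller E2-2 sites carried taller Mtg16 sites. Across 2161 shared E2-2 peaks on chromosomes 1 to 22, X and Y with a Mtg16 summit, the heights had a Spearman rho of 0.63. This is a correlation across sites of 1 library pair, and sites are not independent replicates. The median Mtg16 height was 16 at the 102 sites with an E2-2 height of 100 to 119, 18 at the 46 sites of 120 to 149 and 29 at the 64 sites of 150 or more. At 26 of the 2161 shared E2-2 peaks the Mtg16 height was above the E2-2 height. These were not all separate places. On chromosome 16 several lay between 33237815 and 33241270, where the Mtg16 peaks from 33239149 and from 33240662 each counted at more than 1 E2-2 peak.

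**Figure D4:**
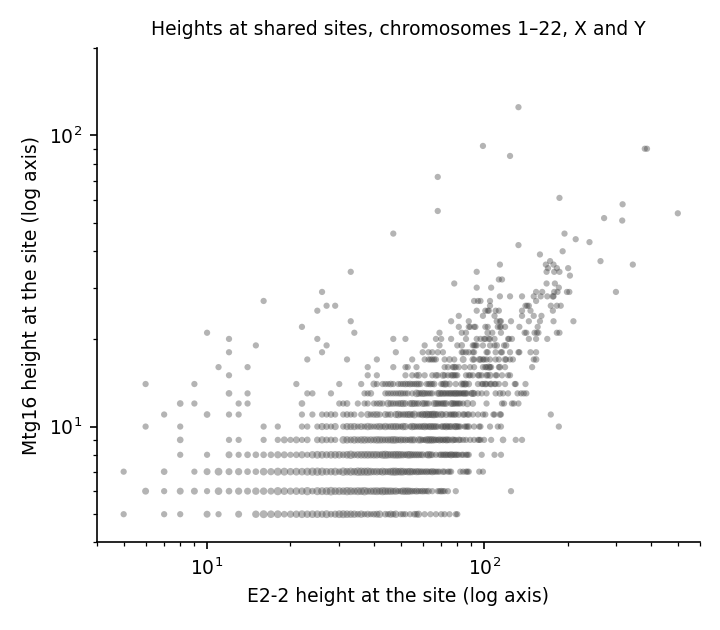
Mtg16 height (y axis, log scale) against E2-2 height (x axis, log scale) at the 2161 shared E2-2 peaks on chromosomes 1 to 22, X and Y; each point is a pair of heights and its size grows with the number of sites that have it. Median Mtg16 height is 16 at E2-2 heights of 100 to 119 and 29 at 150 or more.

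The 10 pairs with the lowest rank sums had Mtg16 scores of 734 to 1553, and an E2-2 score of 3100 in each. A region on chromosome 16 (Mtg16 peak 70466596 to 70467093, E2-2 peak 70466416 to 70467910) had a Mtg16 height of 90 and an E2-2 height of 387, with both tallest summits at 70466755. A region on chromosome 19 (Mtg16 peak 947596 to 948203, E2-2 peak 946720 to 948474) had heights of 90 and 380 and a common summit at 947885. Another on chromosome 19 (Mtg16 peak 17416087 to 17416514) had heights of 58 and 316. On chromosome 1, the Mtg16 peak from 182453674 to 182454141 had a height of 52 within an E2-2 peak of height 271. On chromosome 16, the Mtg16 peak from 89044832 to 89045737 had a height of 37 inside an E2-2 peak that ran from 89041623 to 89045875 and reached a height of 263. The tallest subpeak of the E2-2 list, with a height of 500, lay in the E2-2 peak on chromosome 7 from 102252850 to 102255832, which held a Mtg16 peak of height 54. Summits of the 10 pairs lay 0 to 20 bp apart. Annotation of hg19 was not used here, so the genes at these regions are not stated.

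The 10 highest-scoring E2-2 peaks, with scores of 3137 to 3233, all overlapped a Mtg16 peak, at Mtg16 scores of 148 to 371. They were not the tallest E2-2 peaks. Their heights were 63 to 152, against E2-2 heights of 195 to 500 in the 10 pairs with the lowest rank sums. The first was on chromosome 6 from 44562088 to 44562860, with an E2-2 height of 152 and a Mtg16 height of 21 at the same summit. The second was on chromosome 10 from 45458407 to 45459335, where the summits lay 260 bp apart. Of the 10 highest-scoring Mtg16 peaks, 9 overlapped an E2-2 peak, each at an E2-2 score of 3100. The exception was the highest of all, on chromosome 9 from 10173 to 10453, with a score of 3100, a height of 264 and no E2-2 peak. The next separate Mtg16 peak by score was on chromosome 6 from 50675964 to 50676180, with a score of 153 and a height of 16. The highest-scoring E2-2 peak without a Mtg16 peak was on chromosome 9 from 140063626 to 140065589, with a score of 1913 and a height of 51. The next was on chromosome 15 from 58745962 to 58747097, with a score of 1871 and a height of 49.

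Sites of both proteins were densest on the same chromosomes. Between the first and last peak of either list, chromosome 22 held 18.6 E2-2 and 3.11 Mtg16 peaks per Mb and chromosome 19 held 17.7 and 2.98. Chromosome 4 was the lowest autosome for both, at 3.87 and 0.440 peaks per Mb. The number of Mtg16 peaks per 100 E2-2 peaks ranged over the 22 autosomes from 10.7 on chromosome 13 to 19.4 on chromosome 16, with a median of 14.1. Chromosome X held 317 E2-2 and 18 Mtg16 peaks, or 5.68 per 100. Over the autosomes the share of E2-2 peaks with a Mtg16 peak ran from 5.68% on chromosome 4 (4.23 to 7.58) to 14.5% on chromosome 22 (11.96 to 17.4). On chromosome X it was 3.47% (1.95 to 6.11).

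**Figure D5:**
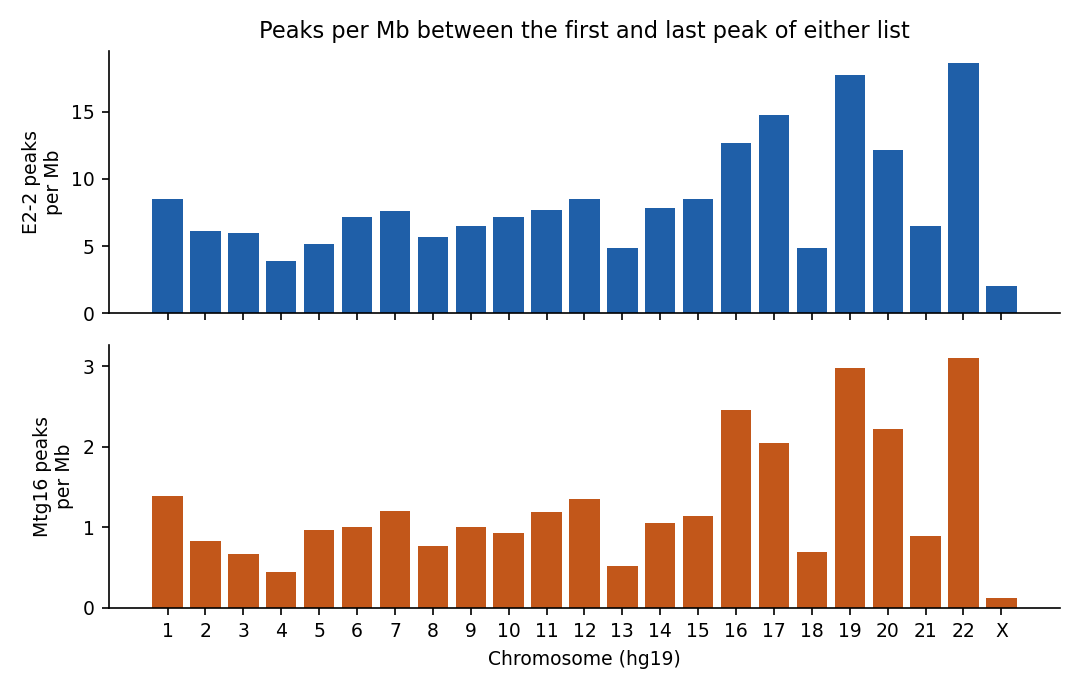
E2-2 peaks per Mb (top) and Mtg16 peaks per Mb (bottom) on chromosomes 1 to 22 and X (x axis, hg19), each over the stretch between the first and last peak of either list; bars are single values from 1 library each and the y axes differ. Chromosome 22 is the highest in both panels, at 18.6 and 3.11 peaks per Mb.

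Shared E2-2 peaks were spread over 937 of the 2452 windows of 1 Mb that held a peak of either list. The 8 windows with the most shared E2-2 peaks held 108 of 2177, or 4.96%. The window from 68000001 to 69000000 on chromosome 16 held 16 shared E2-2 peaks among 41 E2-2 peaks, and all 18 of its Mtg16 peaks were shared. The window from 85000001 to 86000000 on chromosome 16 held the most E2-2 peaks of any, 93, of which 15 were shared. The windows from 2000001 to 3000000 on chromosome 19 and from 105000001 to 106000000 on chromosome 14 held 15 and 13 shared E2-2 peaks among 76 and 56. Over all 2452 windows the mean was 8.70 E2-2 peaks and 0.888 shared ones.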

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

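The overlap exceeded random placement under each of the 12 alternatives tried for each list, with ratios to the random mean from 28.8 to 369. The share of Mtg16 peaks that overlap an E2-2 peak was 93.5% at or above the median scores, 97.6% with a minimum score of 100, 71.3% with an overlap of at least 50% of the shorter peak, 66.9% with tallest summits within 200 bp and 74.2% with subpeaks. It moved to 6.89% against a random 10% of the E2-2 peaks, by construction, since fewer E2-2 peaks were left, and was 59.2% against the 3206 E2-2 peaks of highest score. Of those 3206 E2-2 peaks 56.1% overlapped a Mtg16 peak, against 10.2% of all E2-2 peaks. At or above the median scores the ratio of median scores of shared to separate peaks was 5.81 in the E2-2 list, against 9.24, and 1.498 in the Mtg16 list, against 1.57. This setting drops weak peaks from both lists at once. The median scores of separate peaks, 99.7 for E2-2 and 55.6 for Mtg16, lay under the cuts of 110.9 and 69.9, so these medians had to rise. How much of the change in the ratios this accounts for was not tested. The median summit distance was 30 bp at an overlap of at least 50% and 25 bp at or above the median scores. It stayed under the random median of 105.5 bp with summit positions exchanged among peaks and of 261 bp with each Mtg16 peak moved within reach of its E2-2 peak (one-sided permutation p = 0.0010 for both). Of the 32 alternatives, 28 stayed within 1.5 times the main share, within the interval of the score ratio or on the same side of the summit test. This count holds each overlap alternative for both lists. Other random placements leave the observed share unchanged by construction, so for them only the comparison with random placement could change. The placements that moved peaks by 10 to 100 kb, shifted whole chromosomes or left out empty stretches, the subsets of E2-2 peaks, and the exchanged and moved summit positions were chosen after seeing the data. The alternatives for gene lists, genomic distribution, motifs and placement matched on distance to a gene start were not run, since no hg19 annotation or sequence was used here. No paired analysis was possible because each antibody has 1 library. Leaving out a replicate was not possible for the same reason. The unknown read depth limits any statement on E2-2 peaks that lack a Mtg16 peak: a Mtg16 signal under the caller's limit there was not detectable.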

Other observations

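The removal of contigs, chromosome starts and wide peaks, the heights by class under a call limit of 7, the call limit of 5, the spread without 3 sites and the moves of 10 to 100 kb were chosen only after the result was seen. E2-2 peaks that carried a Mtg16 peak had more E2-2 peaks around them. Within 50 kb, shared E2-2 peaks had 4.82 ± 4.07 other E2-2 peaks (SD over 2177 peaks) and E2-2-only peaks 3.34 ± 3.51 (SD over 19150 peaks). If E2-2 height were the whole cause, the difference at equal height would include 0. At equal height it was 0.733 peaks (95% bootstrap interval 0.434 to 1.04, over 1808 shared peaks with a match). The other 369 shared peaks had no E2-2-only peak of the same height. The interval lay above 0, but it treats peaks as independent although nearby peaks count one another, so it is likely too narrow. Peaks matched on height may also still differ in strength. The difference argues against height as the whole cause but does not exclude it. A hypothesis that stays open is that Mtg16 is found more often where E2-2 sites cluster. A higher local background in such regions was not tested.

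The Mtg16 heights looked like a scaled version of the E2-2 heights. At the 212 shared sites with an E2-2 height of at least 100, the Mtg16 height was a median 15.3% of the E2-2 height (interquartile range 12.3 to 18.4). With Mtg16 counts in proportion to E2-2 height (16.2%, the ratio of the summed heights) and a call from 7 upward, 31.5% of E2-2 peaks of height 30 to 39 and 91.8% of those of height 60 to 79 would be called, against 32.1% and 89.3% observed. Of the limits from 5 to 10, 7 came closest to the observed share at heights of 30 to 49, with 40.5% against 40.2%. The match at 30 to 39 is therefore not an independent check. At heights of 10 to 19 the observed 2.11% was above the 0.978% expected, and at 20 to 29 the observed 12.5% was above the 10.2% expected. At 80 to 99 the observed 95.1% was below the 98.7% expected. The test fixed before the result was seen took E2-2 peaks of height 30 to 49. A detection limit would give a share between the 27.5% and 55.5% of call limits of 8 and 6. The observed share was 40.2% (37.9 to 42.5), so that rule was met. The Mtg16 list did hold lower heights, down to 5, and 32.1% of the Mtg16 peaks with a height were at 5 or 6. Heights come from the subpeak lists, whose lowest height was 5 for both libraries. In addition, 69 called Mtg16 peaks had no subpeak, so 5 need not be the limit of the peak caller. A limit of 5 would give 70.8%, well above the share observed, so whether a detection limit accounts for the E2-2 peaks without a Mtg16 peak stays open.

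Contigs, chromosome starts and peaks wider than 2 kb held only 40 of the 3206 Mtg16 peaks and 87 E2-2 peaks, and 2242 of the 3166 other Mtg16 peaks were shared. Pile-ups elsewhere were not tested. Reads of the E2-2 library in the Mtg16 library would leave only counting noise around the proportion. The variance around the better of a fitted straight line and a power law was 4.73 times the counting variance of both heights (95% bootstrap interval 1.69 to 8.84). Without 3 sites more than 5 counting SDs from the proportion it was 1.77 times (1.38 to 2.14), and both intervals lay above 1. The interval of 1.69 to 8.84 reaches below the 2 set beforehand. Reads of the E2-2 library and joint occupancy by both proteins therefore cannot be told apart at these sites. Signal that open chromatin gives with any antibody stays open too, because the series holds no library of an unrelated antibody. The input was not analysed here.

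The 3 sites far from the proportion were on chromosome 3 from 64682132 to 64682261 (heights 125 in Mtg16 and 133 in E2-2), on chromosome 2 from 33141270 to 33141708 (85 and 124) and at the start of chromosome 5 from 9987 to 11808 (61 and 187). On the unplaced contig GL000225 the Mtg16 list had 14 peaks, of which 5 were shared, and the E2-2 list 6. Their Mtg16 heights reached 147, with a median score of 56.7. The Mtg16 peak at the start of chromosome 9, from 10173 to 10453, had the highest score and height of its list (3100 and 264).

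The 908 Mtg16 peaks without an E2-2 peak had low scores, and weak calls placed without regard to E2-2 sites would lie near E2-2 peaks only as often as random positions. Of these peaks 15.1% (12.9 to 17.6) had their midpoint within 5 kb of an E2-2 peak, against a mean of 7.31% and at most 10.0% in 1000 random placements. This argues only against an even spread along each chromosome, since these placements ignore the local density of sites. With moves of 10 to 100 kb the mean was 11.1% and the maximum 14.7%, so part of the excess went with the region. The observed 15.1% was still above all 1000 of these moves. Weak calls in accessible regions and Mtg16 sites independent of E2-2 both stay open. The 1 Mb window with the most such peaks, 10, ran from 2000001 to 3000000 on chromosome 1.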
